A study of Mus musculus with 20 samples.

How the data were processed

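The series measured histone marks and RNA in cultured mouse germline stem cells (GSCs), the in vitro counterpart of spermatogonial stem cells, grown on fibroblast feeder cells. Control cells carried floxed Kmt2b alleles and the inducible Rosa26-CreERT2 (F/F), and were mock-treated with ethanol. Knockout cells (FC/FC) came from the same genotype after 4-hydroxytamoxifen (4-OHT) at 1 μM, and cells were harvested 6 days after treatment, per the labels' protocols. H3K4me3, H3K27me3, input DNA and RNA were each measured in 2 control and 2 knockout libraries. H3K9me3 was measured in 2 control libraries with 2 inputs of its own, made with another library kit (ThruPLEX in place of NEBNext), per the labels' protocols. The harvest day and treatment of the cells behind the H3K9me3 libraries and their inputs are not given.

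The deposited chromatin table holds log2 RPM (reads scaled to the mapped reads of the library) for 1 window per gene in 16 libraries, as calculated by the authors. The size and place of the window are not stated, and the values were not divided by input. The deposited RNA table holds log2 RPM per gene in 4 libraries, not divided by gene length. Both tables use the mouse build mm10, and CASAVA 1.8, Trim Galore 0.4.0, Bowtie 1.1.1 and TopHat2 2.0.14 were used, per the submitters' processing notes, which give neither their roles nor the strand setting of the RNA counts. In both tables, 2 to the power of a value was a whole multiple of a fixed step within each library, and the lowest value stood at 0.9 of a step, which marks genes with no read. The step gave the mapped reads of each library, and 100.0% of values came out as whole reads within 0.1. There are 25965 genes in the chromatin table and 25067 in that of RNA, all of them also in the former. By symbol and position, 20515 and 20001 genes matched the reference names, 2371 and 2295 more matched by an older symbol, and 3079 and 2771 did not match. No read fell in 662 windows in any of the 16 chromatin libraries.

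Depth ran from 3830045 mapped reads (H3K4me3 knockout replicate 1) to 63537169 (an H3K9me3 input), and 1 read was worth between 0.0157 and 0.261 RPM. Intervals at 95% around shares are exact binomial (Clopper-Pearson) over windows. They treat windows as independent, which they are not, and do not cover variation between libraries.

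Each mark, the input and the RNA were tested separately between the 2 control and 2 knockout libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on the log2 values as deposited. The tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, and an adjusted p under 0.05 was a call. Windows with a mean of at least 1 RPM were tested in the chromatin comparisons, and genes with a mean log2 RPM of at least 0 in the RNA. The input was tested over the windows kept for H3K4me3. No replicate block was used. Because the unit turned out to be log2, the count model foreseen for read counts was not used.

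Promoter classes were set in control cells from each library over its same-numbered input on the log2(RPM + 0.5) scale. A window carried H3K4me3 at a ratio of at least 1.5 in both control libraries, and H3K27me3 at a ratio of at least 1 in both. Windows with both marks were called bivalent, and the others H3K4me3 only, H3K27me3 only or neither. Since the control libraries also enter the genotype tests, the classes were also set from the knockout libraries. Classes were compared with Fisher's exact test on the calls and with limma's camera set test at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests a set against no change and not against other genes. The set tests of the 3 comparisons (bivalent promoters in H3K4me3, and windows that lost H3K4me3 in H3K27me3 and in RNA) were adjusted together, which was decided after their unadjusted values were seen. Genes are not independent replicates, so these p-values describe the libraries at hand.

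Gene lists were fixed before the data were examined, as were the tests, the classes and most of the other settings. There were lists of embryonic transcription factors, embryonic signalling ligands, Hox genes, pluripotency, undifferentiated and differentiating spermatogonia, meiotic prophase, spermatids, the piRNA pathway, H3K4 methyltransferase complexes, Polycomb complexes, H3K4 and H3K27 demethylases, DNA methylation and germline silencing, ribosomal proteins, p53 targets, interferon response, cell cycle and oestrogen response. The list of signalling ligands also holds secreted antagonists of ligands, such as Chrd and Sfrp2. Another set of lists marks cells other than germ cells, namely fibroblast feeder markers, Sertoli and Leydig markers and blood and macrophage markers, with germ cell markers against them. Adjustment was over the 22 lists tested in H3K4me3 and in RNA, and over the 14 with at least 3 tested members in H3K27me3.

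Named genes followed a fixed rule. It took Kmt2b, the 8 largest decreases and 8 largest increases among called genes whose groups did not overlap and whose mean was at or above the median, and up to 3 called members of each list by adjusted p. Predicted genes and some gene families were left out of the 8 and 8. Genes named outside this rule are said to be chosen after their values were seen. H3K9me3 was tested with limma against its own inputs on log2(RPM + 0.5), with no comparison between genotypes.

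The test scripts were tested on simulated data with a known change in up to 50 genes per direction and size. For H3K4me3, 95.9% of 4-fold decreases and 47.9% of 2-fold decreases were recovered among 15617 windows, with 8 false calls among 150. For H3K27me3, 39.5% of 4-fold decreases and 56% of 4-fold increases were recovered among 4867 windows, against 0% and 2% at 2-fold. For RNA, 97.9% of 2-fold decreases and 98% of 2-fold increases were recovered among 14095 genes, with 9 false calls among 197. The simulated spread between replicates (dispersion) was fixed within a comparison, at 0.03 for H3K4me3, 0.0927 for H3K27me3 and 0.0085 for RNA. The real RNA replicates had a chi-square per degree of freedom of 23.7 in knockout and 2.24 in control cells. The H3K4me3 knockout libraries had median changes of -1.66 and -0.89 at bivalent promoters. The rates of recovery and of false calls may therefore not hold for these libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

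Alternatives covered the filter on low values, 3 other scalings (median centring, quantile normalization and, for H3K4me3 and input, the median of ribosomal protein promoters), division by input, the pseudocount, limma without the trend, limma voom on whole reads, a replicate block, a 2-fold minimum, the class thresholds, the inputs of the other kit and leaving out each library in turn.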

Results

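The series asks what the H3K4 methyltransferase Kmt2b does to histone marks and RNA in cultured spermatogonial stem cells. It holds 20 libraries, with 2 per group, and knockout and 4-OHT exposure go together in every comparison. Mapped reads ran from 3830045 to 18035122 for H3K4me3, from 10538531 to 14810135 for H3K27me3, from 10967790 to 14405261 for the matched inputs, from 41099186 to 63537169 for H3K9me3 and its inputs, and from 38458010 to 45771857 for RNA. The H3K4me3 knockout libraries were unequal, with 3830045 reads and 20.7% of them in gene windows in replicate 1, and 16578722 and 27.2% in replicate 2. The control libraries had 10360152 and 18035122 reads, with 25.6% and 29.0% in gene windows. Over rows with a mean of at least 1 RPM in the pair, log2 values of replicates correlated at 0.977 and 0.915 for H3K4me3 in control and knockout. They correlated at 0.832 and 0.87 for H3K27me3, at 0.658 and 0.73 for the matched inputs, and at 0.997 and 0.99 for RNA. That filter left 15777 and 15244 windows for H3K4me3, but 546 and 440 for the matched inputs. Over the windows tested, the matched input replicates correlated at only 0.255 and 0.259. By the same filter the H3K9me3 control libraries correlated at 0.443 over 819 windows, and their inputs at 0.988 over 31 windows. The RNA knockout replicates differed by more than counting error, with a chi-square per degree of freedom of 23.7 over genes, against 2.24 for the RNA control replicates and 2.55 for the H3K4me3 knockout replicates.

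The targeted gene was measured first. Kmt2b, listed under its older symbol Wbp7 (mm10 chromosome 7, 30568858 to 30588726), gave 146 ± 5.62 RPM of RNA in control cells and 158 ± 37.6 RPM in knockout cells (SD, n = 2), with a log2 change of 0.09 (SE 0.16). H3K4me3 at its promoter was 26.0 ± 0.61 and 29.5 ± 6.69 RPM (SD, n = 2), with a log2 change of 0.16 (SE 0.23). Neither change passed limma's test (adjusted p = 0.798 and 0.765), and the direction turned with the scaling or the library left out. For RNA, the log2 change was 0.34 without knockout replicate 1 and -0.15 without knockout replicate 2. Each of these fits left 1 knockout library, so its spread came from the control pair alone. Reads summed over a gene do not show the loss of single exons, so these values do not check the deletion.

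H3K4me3 was lower in the knockout at the promoters of many developmental genes. Brachyury (T), a mesoderm transcription factor, went from 13.3 ± 1.53 to 2.46 ± 2.74 RPM (SD, n = 2), a log2 change of -3.13 (mm10 chromosome 17, 8434423 to 8442496; limma adjusted p = 7.45e-05). The growth factor gene Fgf4 fell by 3.12 on the log2 scale, the forebrain factor gene Six3 by 3.12, Wnt3a by 2.34, the endoderm factor gene Sox7 by 2.30 and the BMP family gene Gdf7 by 2.28. These sizes lean on the shallow knockout replicate 1, which held 2 reads at T, 1 at Fgf4, 0 at Six3, 4 at Wnt3a, 4 at Sox7 and 3 at Gdf7. Without it the log2 changes were -1.59 at T, -1.82 at Fgf4, -2.31 at Six3, -1.58 at Wnt3a, -1.28 at Sox7 and -0.68 at Gdf7, and Gdf7 was no longer called (limma adjusted p = 0.228). The gene for the primitive streak factor Mixl1 went from 19.6 ± 1.77 to 6.62 ± 5.31 RPM (SD, n = 2). Among the strongly marked promoters, Bok, a gene of the BCL2 family, went from 28.6 ± 2.43 to 13.0 ± 6.90 RPM (SD, n = 2), and Fkbp1b, She, the cannabinoid receptor gene Cnr1, Ism1, Ism2, Zdhhc2 and Shisa3 had log2 changes between -1.26 and -1.10. Without knockout replicate 1 these 7 lay between -0.79 and -0.38, Mixl1 at -0.91 and Bok at -0.67, and Fkbp1b (-0.59) and Cnr1 (-0.38) were no longer called (limma adjusted p = 0.0613 and 0.203). The only increases under the naming rule were at Yipf3 (log2 change 0.52) and Polr1c (0.51), whose starts lie side by side on chromosome 17 (46248080 and 46248054), so these values are not independent.

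Of 90 embryonic transcription factors tested, 28 lost H3K4me3 and 61 did when adjusted over the list alone, with a mean log2 change of -1.16 (limma's camera adjusted p = 1.54e-12, or adjusted p = 0.875 with an estimated correlation). Of 44 embryonic signalling ligands, 11 lost the mark, or 31 adjusted over the list alone, with a mean of -1.13 (camera adjusted p = 5.13e-09, or adjusted p = 0.875 with an estimated correlation). Among 20 pluripotency genes, Fgf4, Tdgf1 (-1.66) and Dppa5a (-2.01) lost the mark, also 3 adjusted over the list alone, with a list mean of -1.03 (camera adjusted p = 0.00606). Among 36 Hox genes, Hoxd13 (-1.75), Hoxc8 (-1.75) and Hoxb9 (-1.08) lost it, 3 adjusted over the list alone, with a mean of -0.85 (camera adjusted p = 0.0096), which turned to 0.11 under quantile normalization. Knockout replicate 1 had 3 reads at Hoxc8, and without it the log2 change was -0.08 at Hoxc8 and -0.51 at Hoxb9 (limma adjusted p = 0.921 and 0.214), and -0.84 at Dppa5a (adjusted p = 0.289). The Sertoli and Leydig markers had a mean of -1.25 (camera adjusted p = 0.0202), with Cldn11 (-1.67) called among 9 and 3 adjusted over the list alone. For these last 3 lists, too, the adjusted p was 0.875 with an estimated correlation. Under quantile normalization 4 embryonic transcription factors and 5 ligands were called lower, with list means of -0.31 and -0.39. The pluripotency and the Sertoli and Leydig lists then had means of -0.15 each and 0 lower calls, and both lost their camera call (limma's camera adjusted p = 0.31 for both). Camera did not match these lists on H3K4me3 level. Among promoters with H3K4me3 only, the median log2 change was -1.52 at a mean log2 RPM up to 1.66, and -0.26 between 3.97 and 4.08. Loss at these lists is therefore not told apart from a low level of the mark.

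Germline genes were among the losses too, but not more often than other windows. In each germline list the share called lower was under the 9.9% of all windows tested. T and Lhx1 (-1.03) were called among 31 genes of undifferentiated spermatogonia, or 1 adjusted over the list alone, and the receptor gene Kit (-0.91) among 17 of differentiating spermatogonia, or 0 adjusted over the list alone (2 lower at an unadjusted p under 0.05 in limma). The cyclin gene Ccna1 (-1.21) and Terb2 (-1.43, listed as 4933406J08Rik), which acts in meiotic telomere attachment, were called among 38 genes of meiotic prophase, 2 adjusted over the list alone. Adam2 (-1.76) was called among 17 spermatid genes, 1 adjusted over the list alone, and Tdrd6 (-1.27) among 26 of the piRNA pathway, 0 adjusted over the list alone (2 lower at an unadjusted p under 0.05 in limma). Dppa5a was also the member called among the 11 germ cell markers, 1 adjusted over the list alone. Without the shallow knockout replicate 1, limma no longer called Kit (-0.43), Ccna1 (-0.69), Terb2 (-0.75), Adam2 (-1.04) or Tdrd6 (-0.81), with adjusted p between 0.0812 and 0.232. The camera adjusted p of these 6 lists lay between 0.104 and 0.943. Under quantile normalization the germ cell markers and the piRNA pathway were instead called above other genes (limma's camera adjusted p = 0.0093 each), with means of 0.29 and 0.24.

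The feeder markers had 4 of 26 promoters lower, 6 adjusted over the list alone, Lox (-2.14), Fap (-1.89) and Vim (-1.16) among them (mean -0.70, camera adjusted p = 0.152). Under quantile normalization the feeder mean turned to 0.33, with 1 lower and 3 higher calls. Pgr (-2.25), Cyp26a1 (-1.28) and Greb1 (-1.17) were lower among 12 oestrogen response genes, 4 adjusted over the list alone (camera adjusted p = 0.107). Perp (-1.33) was lower among 24 p53 targets, 0 adjusted over the list alone (5 lower at an unadjusted p under 0.05 in limma), and Fcgr3 (-2.04) among 3 blood and macrophage markers, 2 adjusted over the list alone (camera adjusted p = 0.749 and 0.0914). Without knockout replicate 1, which held 5 reads at Lox, 6 at Pgr and 4 at Fcgr3, the log2 changes were -1.38 at Lox, -1.59 at Pgr and -1.43 at Fcgr3. Fap (-1.07), Greb1 (-0.51) and Perp (-0.77) were no longer called (limma adjusted p = 0.125, 0.293 and 0.146). Ribosomal protein genes kept more of the mark than other genes, with a mean of 0.09 that became -0.07 when scaled to their own median (camera adjusted p = 6.09e-13, or adjusted p = 0.875 with an estimated correlation). Genes of H3K4 methyltransferase complexes (mean 0.04, or -0.12 under ribosomal scaling) and cell cycle genes (mean -0.07, or 0.14 under quantile normalization) also lay above other genes (camera adjusted p = 0.00544 and 0.0202, or adjusted p = 0.875 for both with an estimated correlation). Both lost that call under quantile normalization (camera adjusted p = 0.11 each), and cell cycle genes also under ribosomal scaling (camera adjusted p = 0.058). Of these last 3 lists limma called 0 of 79, 0 of 18 and 0 of 28 members, with 3, 0 and 0 at an unadjusted p under 0.05. No member was called in the lists of Polycomb complexes, demethylases, DNA methylation and germline silencing or interferon response (0 by limma, with 3, 0, 1 and 2 lower at an unadjusted p under 0.05), and their camera adjusted p lay between 0.0631 and 0.173. Under quantile normalization 7 interferon response genes were called higher. With an estimated correlation 0 of the 22 lists were called by camera, against 8 with the preset one, and 0 by fry (0 and 1 at an unadjusted p under 0.05).

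In all, limma called 1546 of 15624 windows lower and 8 higher, of which 1474 and 1 changed at least 2-fold, and the median log2 change was -0.26. The 2 groups did not overlap at 51.8% of windows, against 33.3% by chance. The input gave 0 calls in limma over the same windows, with 741 at an unadjusted p under 0.05 and 0 by limma voom. The higher calls made up 0.5% of all calls, but 31% under median centring (1430 lower and 642 higher) and 41% under quantile normalization (595 and 414). Without control replicate 1 or without control replicate 2 there were 0 lower calls (694 and 221 windows at an unadjusted p under 0.05 in limma), without knockout replicate 1 there were 894, and without knockout replicate 2 there were 6889.

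The study's title speaks of monovalent and bivalent promoters, and the loss was compared between these classes. In control cells, 1992 windows were bivalent, 12944 carried H3K4me3 only, 549 carried H3K27me3 only and 10480 neither. H3K4me3 fell at 871 of 1991 bivalent promoters tested (43.7%, 95% interval 41.6 to 46) and at 614 of 12943 promoters with H3K4me3 only (4.7%, 4.4 to 5.1), an odds ratio of 15.6 by Fisher's exact test (13.8 to 17.6). T, Six3, Sox7, Gdf7 and Wnt3a were bivalent, while Mixl1, Bok, Fkbp1b and Cnr1 carried H3K4me3 only. Median H3K4me3 at bivalent promoters was 9.31 and 11.8 RPM in the control libraries and 3.13 and 5.55 RPM in the knockout libraries. With only H3K4me3 it was 18.4 and 21.0 RPM against 14.9 and 20.2 RPM. The median log2 changes were -1.30 and -0.16, a difference of -1.14 (limma's camera adjusted p = 1.66e-63 over 3 comparisons of sets). It was an adjusted p = 0.509 with an estimated correlation (unadjusted 0.17). H3K4me3 was also called lower at 34 of 214 windows tested with H3K27me3 only and at 27 of 476 with neither mark. Their median log2 changes were -1.48 and -0.83, so a larger loss than with H3K4me3 only was not particular to bivalent promoters. By the same thresholds in knockout cells, 1138 of the bivalent windows (57.1%) remained bivalent and 767 (38.5%) carried H3K27me3 only, while 787 windows with H3K4me3 only in control cells became bivalent, so that the knockout had 1926 bivalent windows. These moves are crossings of thresholds, and limma called only 38 windows with H3K4me3 only higher in H3K27me3. In limma no odds ratio could be had without either control library, which left 0 lower calls (694 and 221 at an unadjusted p under 0.05).

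**Figure D1:**
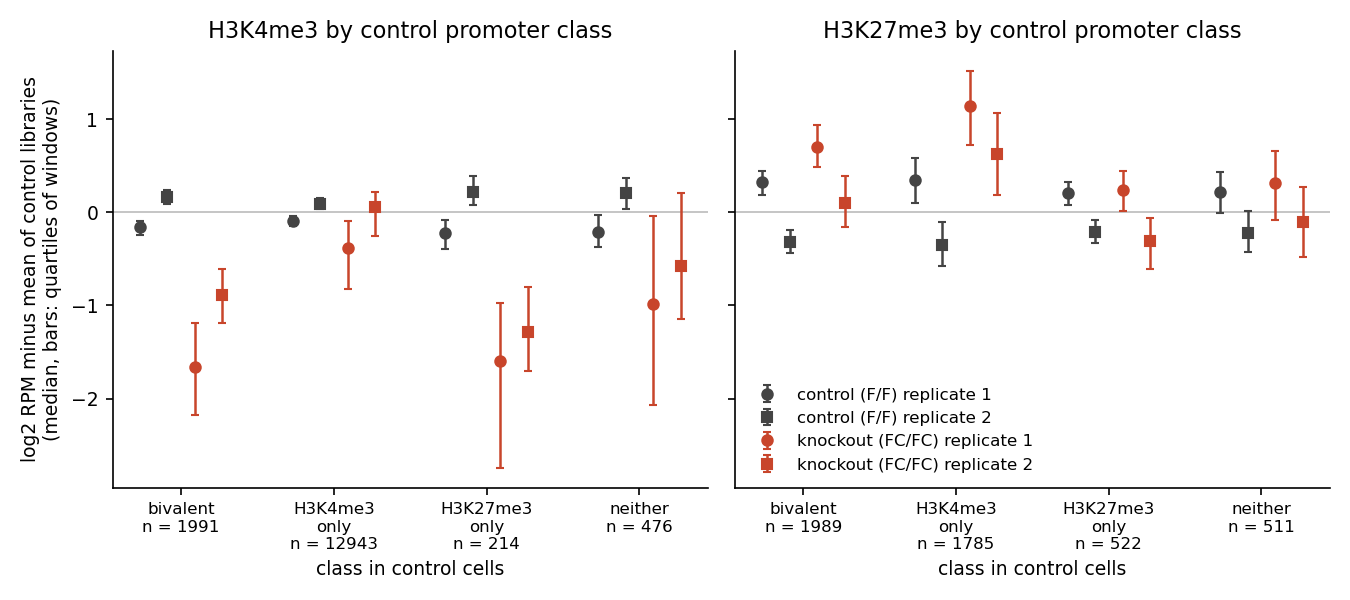
Change of H3K4me3 (left) and H3K27me3 (right) in each library by the class of the promoter in control cells, as log2 RPM minus the mean of the control libraries; points are medians over windows and bars are quartiles, grey for control and red for knockout. At bivalent promoters the knockout medians for H3K4me3 were -1.66 and -0.89, against -0.38 and 0.06 with H3K4me3 only.

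H3K27me3 rose at a small number of promoters in the knockout. Arnt2, a bHLH-PAS transcription factor gene (mm10 chromosome 7, 84246281 to 84409959), went from 1.32 ± 0.84 to 5.87 ± 1.06 RPM (SD, n = 2), a log2 change of 2.30 (limma adjusted p = 0.0171). Igfbp4, which encodes an insulin-like growth factor binding protein, went from 0.571 ± 0.16 to 3.45 ± 0.18 RPM (SD, n = 2), a log2 change of 2.62 (limma adjusted p = 0.00822), and was the member called among 7 oestrogen response genes, 1 adjusted over the list alone. These values rest on 28 and 8 control reads for Arnt2 and 10 and 5 for Igfbp4. The input at Igfbp4 rose as well, with a log2 change of 1.81 (SE 0.59), against -0.20 (SE 0.66) at Arnt2. Over input neither gene was called, with log2 changes of 0.91 (SE 0.52) at Igfbp4 and 2.01 (SE 0.58) at Arnt2 (limma adjusted p = 0.567 and 0.0862), with a pseudocount of 0.5 RPM. With that pseudocount alone the log2 changes were 1.89 (SE 0.42) and 1.87 (SE 0.48), so part of the drop at Igfbp4 came before division by input. Of 4807 windows tested, limma called 38 higher, all of them with H3K4me3 only in control cells, and 0 lower. At an unadjusted p under 0.05 in limma there were 6 lower and 579 higher, and limma voom called 0 lower and 38 higher. The smallest called rise was 3.86-fold. The class rests on low H3K27me3 in the same control libraries, so that all 38 fall in it follows in part from its definition. The groups did not overlap at 40.1% of windows, against 33.3% by chance. The median change over all windows was 0.45, so that median centring turned the split to 202 lower and 81 higher. No higher call was left in limma without knockout replicate 1 or 2 (0 each, with 125 and 399 at an unadjusted p under 0.05), 1 without control replicate 2, and 152 without control replicate 1. In the self-test 2-fold changes of this mark were rarely recovered, so changes of that size may have been missed.

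Embryonic transcription factors had a mean H3K27me3 change of 0.47 over 93 genes, signalling ligands 0.61 over 42, and Hox genes 0.28 over 30. Under median centring these means were -0.11, 0.03 and -0.30. None of the 14 lists was called (0 by camera and by fry, with 2 and 0 at an unadjusted p under 0.05), with camera adjusted p between 0.175 and 0.916. The feeder (0.67), Sertoli and Leydig (0.34), blood (1.16), undifferentiated (0.35) and differentiating (0.42) spermatogonia, meiotic (1.06), spermatid (0.61), piRNA (0.33), pluripotency (0.41), p53 (0.44) and oestrogen (1.05) lists had positive means as deposited, which turned negative under quantile normalization for 6 of them. At the 1343 tested promoters that lost H3K4me3, the median change of H3K27me3 was 0.52, against 0.41 at others. This difference of 0.11 had a camera adjusted p = 0.0162 in limma, but an adjusted p = 0.779 with an estimated correlation. Under median centring the unadjusted camera test did not pass 0.05. Without H3K4me3 knockout replicate 2, whose loss changed the set of promoters, the difference was 0.46, and without knockout replicate 1 it was 0.03.

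RNA rose for many genes that are mainly used in the embryo. Zic1, a neural transcription factor gene (mm10 chromosome 9, 91358058 to 91365810), went from 2.14 ± 0.23 to 9.76 ± 1.40 RPM (SD, n = 2), a log2 change of 2.19 (limma adjusted p = 0.0141). Of 88 embryonic transcription factors with RNA values, 28 passed the filter on low values and were tested. The filter averaged both genotypes, so genes that rose passed more easily. Foxd3 (0.63 RPM), Zic4 (0.73) and Meis2 (0.76) had control means under 1 RPM. Of the 28, 13 rose and 17 did when adjusted over the list alone, among them Six2 (log2 change 1.44) and Irx2 (1.29). The list mean was 0.80 (camera adjusted p = 2.03e-09). With an estimated correlation the adjusted p was 0.395. Under median centring 10 of the 28 were called higher, and under quantile normalization 1 was. From the list of signalling ligands and antagonists, Sfrp2 (0.93), Chrd (0.83) and Dll1 (1.06) rose among 17, or 7 adjusted over the list alone. The mean of that list was 0.43 (camera adjusted p = 0.00209, or adjusted p = 0.574 with an estimated correlation). Hoxb6 (0.75) and Hoxb9 (0.78) rose among 13 Hox genes, or 8 adjusted over the list alone (mean 0.53, camera adjusted p = 0.00015, or adjusted p = 0.395 with an estimated correlation), and neither was called under median centring. Klf2 (1.23), Tbx3 (0.74) and Nr5a2 (0.80) rose among 19 pluripotency genes, 8 higher and 1 lower adjusted over the list alone (mean 0.30, camera adjusted p = 0.00536, or adjusted p = 0.542 with an estimated correlation). Beside these, 4 of 27 fibroblast feeder markers rose, 8 adjusted over the list alone, including Twist1 (0.81), Pdgfra (0.72) and Col1a1, which went from 136 ± 7.52 to 223 ± 29.9 RPM (SD, n = 2). The mean of the feeder list was 0.37 (camera adjusted p = 0.00045, or adjusted p = 0.574 with an estimated correlation).

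**Figure D2:**
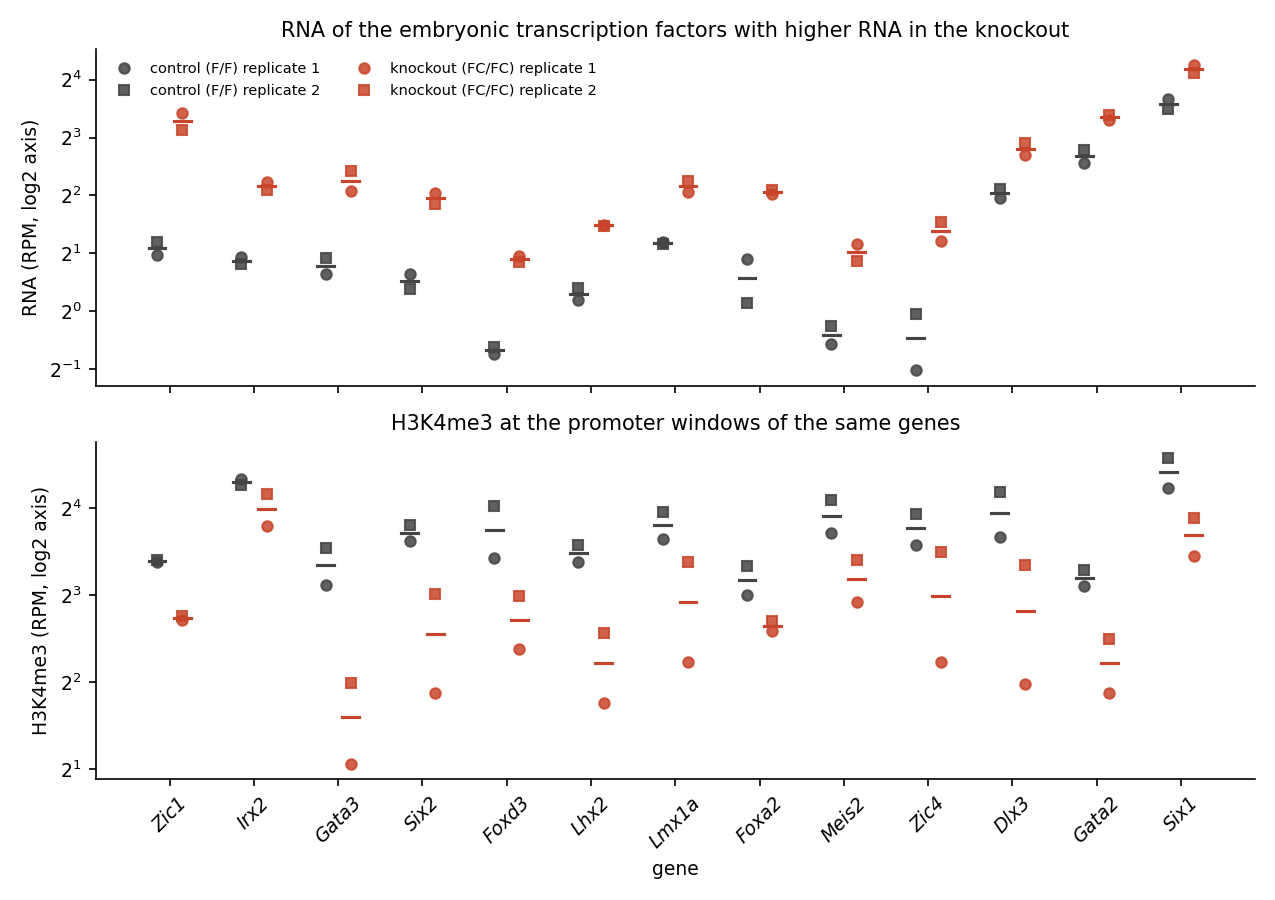
RNA (top) and promoter H3K4me3 (bottom) in RPM on log2 axes for the 13 embryonic transcription factors whose RNA rose; points are libraries, grey for control and red for knockout, and lines are means of 2. The 13 were chosen for higher RNA. All had a negative log2 change of H3K4me3, as did 88 of the 90 list members tested for the mark. The change passed limma's test for 3 of the 13, against 28 of the 90.

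Some genes of differentiating spermatogonia fell in RNA, and some of undifferentiated spermatogonia rose. Stra8, a retinoic acid target needed for meiotic entry, fell from 132 ± 13.6 to 77.4 ± 2.12 RPM (SD, n = 2), a log2 change of -0.76 (limma adjusted p = 0.023). The homeobox gene Esx1 on chromosome X fell from 36.3 ± 1.61 to 18.9 ± 1.29 RPM (SD, n = 2), and the retinoic acid binding protein gene Crabp1 by 0.59 on the log2 scale. These 3 were called among 17 genes of differentiating spermatogonia, 5 lower and 1 higher adjusted over the list alone (mean -0.27, camera adjusted p = 9.06e-07, or adjusted p = 0.395 with an estimated correlation). Of 32 genes of undifferentiated spermatogonia, 5 rose and 13 did when adjusted over the list alone (mean 0.31, camera adjusted p = 0.000238, or adjusted p = 0.574 with an estimated correlation). Among them, Gfra1, the GDNF receptor gene, went from 31.8 ± 0.63 to 48.9 ± 0.25 RPM (SD, n = 2), Neurog3 had a log2 change of 0.78 and Nanos2 of 0.93. Nanos2 was also the member called among the 12 germ cell markers, 1 adjusted over the list alone (camera adjusted p = 0.784). Fabp9 (-1.65) fell among 15 spermatid genes, 1 adjusted over the list alone (camera adjusted p = 0.781).

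Of 20 interferon response genes, 6 rose, or 13 adjusted over the list alone, with the RNA sensor gene Ifih1 at 1.07, Xaf1 at 1.37 and Gbp3 at 0.69 (mean 0.50, camera adjusted p = 5.49e-06, or adjusted p = 0.395 with an estimated correlation). The p53 targets Cdkn1a (0.65), Bbc3 (1.21) and Pmaip1 (0.52) rose among 23, 3 adjusted over the list alone (mean 0.21, camera adjusted p = 0.227), and none of them was called under median centring. Myb (1.39) rose among 8 oestrogen response genes, 3 adjusted over the list alone (mean 0.40, camera adjusted p = 0.0224, or adjusted p = 0.574 with an estimated correlation).

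Cell cycle genes had a mean of -0.15 over 27, genes of meiotic prophase -0.07 over 40 and ribosomal protein genes -0.03 over 80 (camera adjusted p = 2.39e-06, 0.000804 and 6e-04, or adjusted p = 0.574, 0.574 and 0.894 with an estimated correlation). Limma called 0 members of each, with 6 lower, 10 in either direction and 2 lower at an unadjusted p under 0.05. The H3K4 methyltransferase complexes had a mean of -0.01 and were called by camera at the threshold (adjusted p = 0.05 after rounding, or adjusted p = 0.894 with an estimated correlation), with 0 members called by limma and 0 at an unadjusted p under 0.05. The lists of Polycomb complexes (mean 0.08), demethylases (0.05), the piRNA pathway (0.02), DNA methylation and germline silencing (0.04), Sertoli and Leydig markers (0.07) and blood and macrophage markers (-0.06) had 0 calls in limma (5, 1, 3, 4, 1 and 0 at an unadjusted p under 0.05), and camera adjusted p between 0.252 and 0.784. In limma 13 of the 22 lists were called with the preset correlation and 0 with an estimated one or by fry (0 and 9 at an unadjusted p under 0.05).

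**Figure D3:**
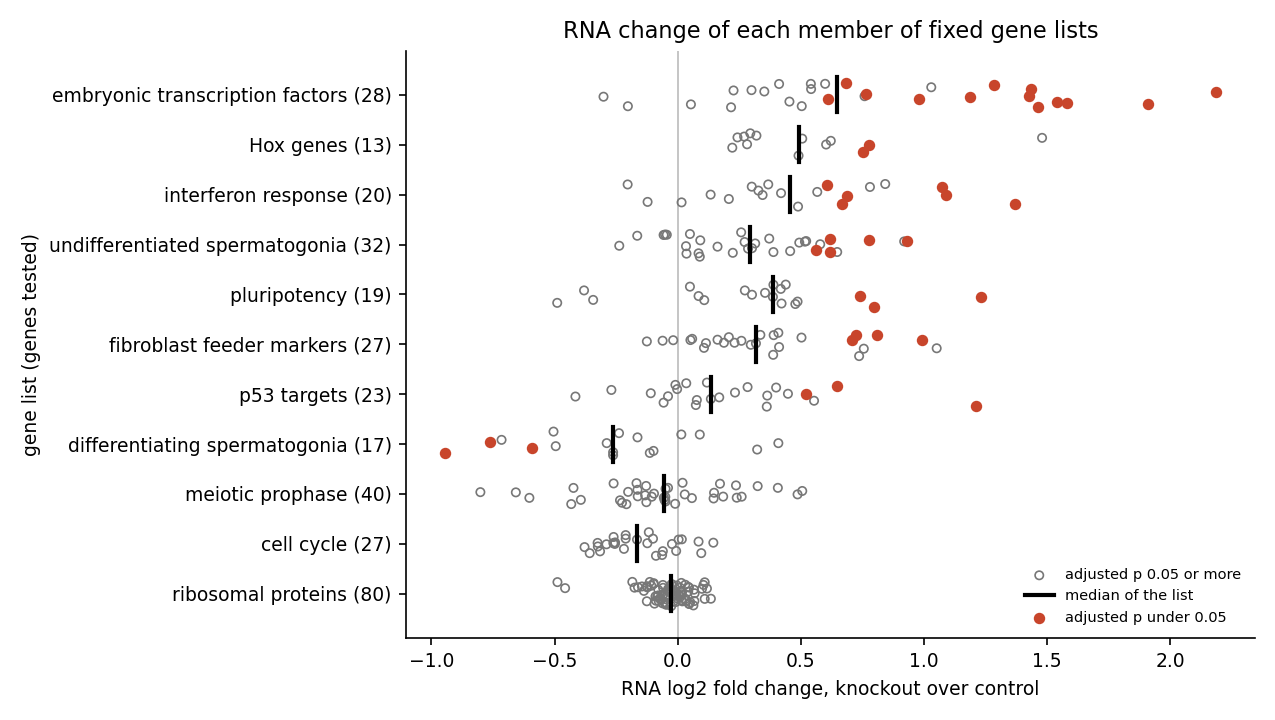
Log2 fold change of RNA, knockout over control, of each tested member of 11 gene lists fixed beforehand; filled points passed limma's test, open points did not, and bars are list medians. The median of the embryonic transcription factors was 0.65, against -0.26 for differentiating spermatogonia and -0.03 for ribosomal proteins.

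Other large RNA decreases were of Larp1b.1, Bex3 (listed as Ngfrap1), the replication licensing inhibitor gene Gmnn (-0.61), Mapk10 and the glycolysis gene Aldoa (-0.54). Increases were of the tubulin gene Tubb2b (1.00), Myh14, the collagen gene Col18a1, which went from 49.7 ± 0.29 to 95.9 ± 7.47 RPM (SD, n = 2), Chrna4, Rgma, Ryr1 and Sox13. Larp1b.1, Aldoa and Tubb2b have close copies or overlapping entries, and how their reads were divided is not known. In all, limma called 44 of 14100 genes lower and 425 higher, 13 and 155 of them by at least 2-fold, and the groups did not overlap for 52.2% of genes, against 33.3% by chance. The higher share of calls was 90.6%, but 70% under median centring (114 lower and 266 higher) and 71.4% under quantile normalization (20 and 50). The median log2 change was 0.06 with all libraries and also without control replicate 1. It was 0.13 without knockout replicate 1 and 0.02 without knockout replicate 2. A fit without 1 library took its spread from the other group alone, so its calls are not comparable with these.

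Genes that lost H3K4me3 were compared in RNA with the other genes. Of the 1546, 633 were tested in RNA, with a median change of 0.18 against 0.06 for other genes (limma's camera adjusted p = 0.145, or adjusted p = 0.779 with an estimated correlation). Limma's fry, which tests the set against no change and not against other genes, gave an adjusted p = 0.115 for a shift in a single direction (unadjusted 0.049) and an unadjusted value of 0.000706 for change in either direction. Under median centring the unadjusted camera test passed 0.05. Of them, 35 rose in RNA (odds ratio 1.96, 95% interval 1.33 to 2.81, Fisher's exact p = 0.000497), and 8 fell where independence gives 2 (odds ratio 4.77, 1.91 to 10.5, p = 0.000667). The first odds ratio turned to 0.69 without RNA knockout replicate 1. The second turned to 0.86 without replicate 1 and 0.52 without replicate 2. Those fits left 1 knockout library and took their spread from the control pair alone, so their calls are not comparable with the main ones. Across 12124 genes, which are not independent replicates, the changes of H3K4me3 and RNA had a Spearman correlation of -0.25, with 0.15 across the 718 bivalent genes and -0.25 across the 11140 with H3K4me3 only. Those of H3K4me3 and H3K27me3 had 0.20 across 4126 genes, with 0.165 across the 1989 bivalent and -0.049 across the 1784 with H3K4me3 only. None of these comparisons was matched on the level of RNA or of H3K4me3. Promoters with little of the mark lost more of it, and the RNA filter averaged both genotypes. A relation between loss of the mark and RNA is therefore not told apart from level.

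H3K9me3, a mark of silent chromatin, was measured in control cells alone. It lay above its inputs at 1558 of 25965 windows and below them at 20605 (limma adjusted p under 0.05). The 1558 held 3 of 1992 bivalent windows (0.15%, 95% interval 0.03 to 0.44), 29 of 12944 with H3K4me3 only (0.22%), 61 of 549 with H3K27me3 only (11.1%) and 1465 of 10480 with neither (13.98%). Of the 1546 windows that lost H3K4me3 in the knockout, 9 carried it (0.58%, 0.27 to 1.1). Chosen after their values were seen, Catsper3, a sperm calcium channel gene (log2 ratio 2.20), and Lhcgr, the luteinizing hormone receptor gene (1.97), stood among the strongest, as did Scgb2b24 (2.41, listed as Abpz), a member of a family with close copies.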

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

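The limma voom counts, the added pseudocount of 0.5, the loss set without H3K4me3 knockout replicate 1, the RNA count without chromosome X and the adjustment over 3 comparisons of sets were chosen after seeing the data. That adjustment moved fry for the RNA of genes that lost H3K4me3 from 0.049 to 0.115, while the camera calls at 0.05 stayed the same. The set tests below are unadjusted. All other alternatives were planned. The planned count model on whole reads was not run. Whole reads could be recovered from the deposited log2 values, and limma voom on them was added in its place. The planned choices among several promoters of a gene changed nothing, since each gene has 1 window. An RNA pseudocount did not apply. Against 1546 lower and 8 higher H3K4me3 windows there were 1010 and 55 with no filter, 663 lower at a mean of at least 5 RPM, 4616 and 4 with ribosomal protein scaling, 386 and 0 over input (2992 at an unadjusted p under 0.05 in limma), 595 and 414 with quantile normalization, 642 higher with median centring, 302 and 1 without the trend, 2587 and 112 with limma voom, and 1 higher at 2-fold. Leaving out 1 library gave 0 to 6889 lower and 2 to 128 higher. Of the lower windows, 1136 remained under median centring, 397 under quantile normalization and 1514 with limma voom. Against 0 lower and 38 higher H3K27me3 windows there were 202 and 81 with median centring, 0 higher at a mean of at least 5 RPM (4 at an unadjusted p under 0.05 in limma), 4 higher over input, 3 with quantile normalization, 98 without the trend, and 0 to 152 without 1 library. The input had 1 lower and 1 higher with quantile normalization and 0 otherwise in limma. Against 44 lower and 425 higher RNA genes there were 210 higher with no filter, 18 and 188 at a mean log2 of at least 2, 114 and 266 with median centring, 20 and 50 with quantile normalization, and 13 and 155 at 2-fold, while limma voom gave 45 and 414. Leaving out 1 library gave 28 to 3095 lower and 227 to 5257 higher. A fit without 1 library took its spread from the other group alone, so its counts are not comparable with the main ones. The cause of the other moves was not tested.

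Replicates share only a number, since the labels do not tie a number to a cell line. Deviations of same-numbered libraries correlated at 0.15 (H3K4me3), 0.06 (H3K27me3), 0 (input) and 0.09 (RNA). With the number as a replicate block there were 4037 lower and 70 higher H3K4me3 windows, 7 and 1206 H3K27me3 windows, and 195 and 1292 RNA genes. For the set comparisons, the 4037 windows called lower with the block then took the place of the main set. With them the RNA difference was 0.14 and the H3K27me3 difference 0.38, and both passed the camera threshold. A block leaves the log2 changes of this balanced design as they were, so these differences moved through the larger set.

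Kmt2b reversed in H3K4me3 with ribosomal protein scaling (0.00) and without knockout replicate 2 (range -0.07 to 0.40), and in RNA with median centring (0.00) and without knockout replicate 2 (range -0.15 to 0.34). No other named gene reversed, but many calls were lost. Of 37 named H3K4me3 calls, all 37 were lost without either control library, 35 without the trend, 30 over input, 23 under quantile normalization and 14 without knockout replicate 1. Of 40 named RNA calls, 26 were lost under quantile normalization, 19 without control replicate 1 and 16 without control replicate 2. Among the 1992 bivalent windows, the count was 1288 at an H3K27me3 threshold of 1.5. Windows with H3K27me3 only numbered 1160 at a threshold of 0.5, 302 at 1.5, 1480 from the knockout libraries and 584 to 981 from 1 control library, against 549. The odds ratio of loss at bivalent promoters ranged from 14.4 to 33.6 over the alternatives that gave one, and the difference of medians (-1.14) did not pass the camera threshold with an estimated correlation. The H3K27me3 difference of 0.11 at promoters that lost H3K4me3 did not pass it with an estimated correlation, with median centring, or without H3K4me3 knockout replicate 1, H3K27me3 control replicate 2 or H3K27me3 knockout replicate 1, and ranged from 0.03 to 0.46 without 1 library. The RNA difference of 0.11 passed the camera threshold with median centring and without H3K4me3 knockout replicate 2, RNA control replicate 2 or RNA knockout replicate 2, and ranged from 0.07 to 0.13 without 1 library. The odds ratios of RNA higher and lower ranged from 0.69 to 3.06 and from 0.52 to 5.35. With an estimated correlation 0 lists were called in H3K4me3 (8) and in RNA (13), with 0 in each at an unadjusted p under 0.05 in limma, and in H3K27me3 between 0 and 1 were called without 1 library. With inputs of the other kit, H3K9me3 lay above input at 1 bivalent window, 7 with H3K4me3 only and 899 with neither, and without 1 library at 3 to 9 bivalent windows and 19 to 47 with H3K4me3 only. Over input neither named H3K27me3 gene was called. H3K4me3 knockout replicate 1 was the shallowest library, with 3830045 reads and 793363 of them in gene windows, while the H3K27me3 libraries held 211222 to 445865 reads in gene windows.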

Other observations

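All values in this paragraph were chosen after they were seen. Chromosome X held 14 of the 44 genes with lower RNA, against 4% of the genes tested (odds ratio 11.3, 95% interval 5.5 to 22.2, Fisher's exact p = 1e-09). Without predicted Gm genes, several of which are near copies of each other, it held 8 of 38 (odds ratio 6.9, Fisher's exact p = 7.1e-05), Esx1, Bex3, Bex2 (-0.90), Ccnb3 (-0.56), Rnf128 (-0.71), Morc4 (-1.10), Cnksr2 (-1.25) and Ct55 (-0.99, listed as 4930502E18Rik). The odds ratio was 5.9 under median centring and 8 under quantile normalization, and 7 X-linked genes rose. Of the 8 windows with higher H3K4me3, 5 (Gm10800, Gm10801, Gm10717, AC242409.1 and Sfi1) had over 10 RPM in the inputs, where only 10 windows did and the median was 0.62 RPM, and the groups overlapped at AC242409.1 and Sfi1. RNA rose for 51 of 719 bivalent genes (7.1%) and 307 of 11140 with H3K4me3 only (2.8%), an odds ratio of 2.69 (1.94 to 3.67, Fisher's exact p = 1.2e-08). Among bivalent genes, RNA rose for 8 of 277 that lost H3K4me3 (2.9%) and 43 of 442 not called for it (9.7%), an odds ratio of 0.28 (0.11 to 0.61, Fisher's exact p = 0.00048). Only 36.1% of bivalent windows were tested in RNA, against 86.1% with H3K4me3 only. The filter averaged both genotypes, so genes that rose passed more easily. Neither comparison was matched on RNA level. Of the 13 embryonic transcription factors that rose, Gata3, Six2 and Dlx3 lost H3K4me3, against 28 of the 90 list members tested for the mark.

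In the weighing that follows, the tests of the shallow library and both tests of feeder RNA were chosen after the result was seen, and the others before. Loss of H3K4me3 was stronger at bivalent than at H3K4me3-only promoters by a difference of medians of -1.14. With classes set on the knockout libraries the difference was -0.91, and without knockout replicate 1 it was -0.94, which argues against regression to the mean and against the shallow library as the whole source. Bivalent promoters carry less H3K4me3, and between promoters of equal level the difference was -0.47 (between -0.55 and -0.36 in 10 levels). This fell between the bounds set beforehand (above -0.3 if level was the source, below -0.5 if not), so level goes with part of the difference and the rest stays undecided. No control library had 4-OHT (0), so the loss of Kmt2b and the drug cannot be told apart.

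RNA of the 28 embryonic transcription factors tested rose with a list mean of 0.80. It stayed at 0.59 or above under quantile normalization and median centring, although the members called fell from 13 to 1 and 10. The list median of 0.65 was above all of 10000 random lists of like expression (percentile 100, median 0.20, highest 0.50). Genes of like expression thus rose as well, against a median of 0.06 over all genes tested. These values argue against scaling and against a general rise of weak genes as the whole source. More RNA from feeder fibroblasts is a candidate source that stays open. By the first criterion, the 10 most abundant feeder markers lay below the embryonic factors by a difference of medians of 0.43, which missed its threshold (permutation p = 0.0536). A second criterion, set only after that, found 8 of the 10 more than 2 SE below the embryonic median, Fn1 (-0.12), Col3a1 (-0.02) and Sparc (0.06) among them, but Col1a1 (0.71) and Xist, which female somatic cells express (4.13 ± 0.03 to 7.13 ± 0.20 RPM, SD, n = 2), rose. With 0 control libraries given 4-OHT, the drug and the loss of Kmt2b cannot be told apart here either.

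H3K27me3 had a median log2 change of 0.45 over tested windows, but the groups were apart at only 40.1% of them (33.3% by chance). The median was 0.14 without control replicate 2, 0.19 without knockout replicate 1 and 0.75 without control replicate 1. At bivalent windows knockout replicate 2 (0.10) lay below control replicate 1 (0.32). Each knockout library lay above the control library of its number there (0.70 against 0.32, and 0.10 against -0.32). The labels do not tie a number to a cell line. The size of the rise depended on the library left out. A common factor per library would move all marked windows alike, yet at equal level bivalent windows lay above those with H3K27me3 only by 0.5 (0.14 to 0.70 in 11 levels), which argues against it as the whole source. Windows with H3K4me3 only gained more than bivalent ones (0.87 against 0.40) by classes set on control libraries, but with classes set on the knockout libraries the difference was -0.03. The larger gain at promoters with H3K4me3 only may therefore come from regression to the mean. With 0 control libraries given 4-OHT, the drug and the loss of Kmt2b cannot be told apart for this mark, and no other biological explanation was tested for it.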
